A study of Medicago truncatula with 24 samples.

How the data were processed

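Per the labels' protocols, plants grew in hydroponics under 16 h of light with 0.5 mM KNO3 before treatment, and their roots were split at 3 weeks of age. RNA was extracted with a miRNeasy kit, and libraries were made with the NEXTFLEX Small RNA-seq kit v3 and size-selected on a Pippin instrument. Per the submitters' processing notes, reads were processed with cutadapt, whose version is not given in the sources used here; the aligner, the counting tool and the origin of the counted sequences are not given in the sources used here either. The deposited files hold whole-number counts per sequence, made by the authors, for the same 427 sequences in each of the 24 libraries, and these deposited counts were used without change. All fits, scalings, family names and tests are from the analysis described here. Of the 427 sequences 84 had no count in any library and 343 had counts, with 340 distinct profiles; lengths were 21 nt (267 sequences), 22 nt (69), 24 nt (60), 20 nt (23), 23 nt (7) and 19 nt (1). The counts summed to 52312029. Counts of replicate libraries differed by more than counting error alone, with a chi-square per degree of freedom of 26.4 to 476.2 over the 24 replicate pairs (sequences with at least 10 counts), so a model with biological or technical spread was needed.

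Families were assigned by sequence, because the files hold no miRNA names. A sequence took a family when it aligned to 1 of 36 conserved mature sequences of 33 families with at most 3 mismatches over at least 18 nt, or when it paired with such a member as its opposite arm (2-nt overhang, at most 3 mismatches, at most 4 GU pairs, at least 17 paired positions). In this way 70 mature and 23 opposite-arm sequences of 31 families were named, 85 of them with counts. The conserved sequences were written from textbook knowledge after the files were seen, and a first opposite-arm rule that found 4 sequences was replaced before any fold change was computed. Sequences without a family are given by their bases alone.

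The main test was edgeR 4.0.16 quasi-likelihood (glmQLFit with robust estimation, glmQLFTest) with TMM scaling, filterByExpr by group (minimum count 10) and Benjamini-Hochberg adjustment over the sequences tested, called at adjusted p under 0.05. Shoot and root libraries (12 each) were fitted apart with 4 group means, and the comparisons between organs used all 24 libraries. Family tests used the same method on counts summed per family together with the unassigned sequences, with scaling factors of their own, adjusted over all of these; the CPM of a family with a single sequence can therefore differ from that of the sequence. CPM are counts scaled to a common TMM-adjusted library total and given as mean ± SD; log2 changes are given ± SE of the fit. Lists of families fixed in advance were the systemic signal (miR2111), phosphate (miR399, miR827), copper (miR397, miR398, miR408, miR857), NF-YA (miR169), auxin (miR160, miR164, miR167, miR390, miR393), phase change (miR156, miR157, miR172), NB-LRR and phasiRNA triggers (miR482, miR1507, miR1509, miR1510, miR2109, miR2118), organ development (miR159, miR165, miR166, miR171, miR319, miR396) and small RNA machinery (miR162, miR168, miR403). They were tested with camera of limma 3.58.1 at a preset correlation of 0.01 and with the correlation estimated, over distinct profiles; a sulfate list (miR395) had too few counts to be tested. Of 14 list calls with the preset correlation 13 were lost with the estimated correlation. The lists were also tested with fry of limma, which asks whether members changed without comparing them with the other sequences. Of the 14 calls fry kept all but the systemic signal in A17 shoots and cra2 shoots (fry adjusted p = 0.162 and 0.527).

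Named items followed rules set before the data were examined: up to 12 called sequences per direction with the largest log2 change and no overlap between the libraries compared (overlap allowed for differences of responses), 16 fixed families as sums whatever their p, the 5 most abundant sequences of each organ, and the 5 smallest p where nothing was called. Called families outside the 16 fixed ones were named because they passed, a choice made after the values were seen. At-least folds use a floor of 3 counts over the side without counts. Where a side had 1 to 3 counts, the ratio of counts per total is given with its exact 95% counting interval. Alternatives chosen before the data were examined were RLE, library-total and upper-quartile scaling, DESeq2 1.42.0 (Wald test), no filter, a filter of at least 10 CPM in 3 libraries, identical profiles entered once, family sums, a replicate block, each library left out, and other sets of libraries in the fit. Thinning to the smallest total, leaving out the miR159 sequence, leaving out the 3 cra2 shoot deficit libraries and the genotype-by-organ test were added after the data had been seen.

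Whether replicate numbers pair libraries was checked by correlating residuals of equally numbered libraries. Only the nitrogen response of A17 roots passed the rule (r above 0.1 in each of 3 pairs, 0.136 to 0.349, each best with its own number), and with the replicate number as a block 55 sequences were called there against 52. The test was tested on simulated data with 20 simulations per comparison, in which 2-fold changes were recovered in 34.6% (A17 shoot response), 62.2% (A17 root response), 25.6% (difference of responses, root), 69.3% and 85.9% (genotype, shoot and root) and 73.2% (shoot against root) of cases, and 4-fold changes in 82.4% to 98.9%. False calls were 3.74% to 6.2% of all calls, and 0 calls had the wrong sign. The simulations drew sequences independently and with the same spread in every group. These rates therefore need not hold for the shoot fits, where the cra2 deficit group spread more than the others. Computation used R 4.3.3, Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.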

Results

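Small RNA libraries of the model legume Medicago truncatula were compared between the wild type A17 and the cra2 mutant, which is affected in the receptor kinase CRA2. CRA2 perceives CEP peptides, hormones made by nitrogen-starved roots. Each root system was split between a local compartment, given 10 mM NH4NO3 (satiety) or 0.05 mM KNO3 (deficit) for 4 days, and a systemic compartment without mineral nitrogen. Shoots and systemic-compartment roots (here "distant roots") of 4-week-old plants gave 8 groups of 3 libraries, 24 in all. That the roots came from the systemic compartment rests on the series design, since the labels of single libraries name only the organ and the local treatment. Of the listed sequences 343 had counts and 84 had none. By sequence, 93 were assigned to 31 miRNA families, which held 97.0% of all counts. Per the labels, nothing says whether the replicates are separate plants, so each p-value measures only the spread between these samples, which may be technical. The CRA2 transcript is not measured by small RNA, so the genotype labels were not checked by it.

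A single miR159 sequence, TTTGGATTGAAGGGAGCTCTA (miR159 targets GAMYB transcription factors), took 72.2 ± 2.83% of the counts in roots and 81.8 ± 3.67% in shoots (mean ± SD, n = 12 libraries each). Next in roots came miR166 TCGGACCAGGCTTCATTCCCC (6.92 ± 1.62%), miR396 TTCCACAGCTTTCTTGAACTG (4.05 ± 1.83%), miR396 TTCCACAGCTTTCTTGAACTT (2.76 ± 0.528%) and miR5213 TACGTGTGTCTTCACCTCTGAA (2.15 ± 0.629%). In shoots the next were TTCCACAGCTTTCTTGAACTT (3.32 ± 1.07%), TCGGACCAGGCTTCATTCCCC (2.80 ± 0.729%), TTCCACAGCTTTCTTGAACTG (1.69 ± 1.17%) and miR2118 TTACCGATTCCACCCATTCCTA (0.86 ± 0.304%). Library totals were 768323 to 1661422 counts in roots and 1494211 to 3919811 in shoots, so 3 counts corresponded to 0.765 to 3.9 CPM (counts scaled to a common library total). No sequence was assigned to miR827, and miR393 (61 counts in 24 libraries), miR395 (74) and miR397 (42) were too rare to test. The levels of miR2111, miR399 and miR408, which set the genotypes apart, are drawn for each library.

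**Figure D1:**
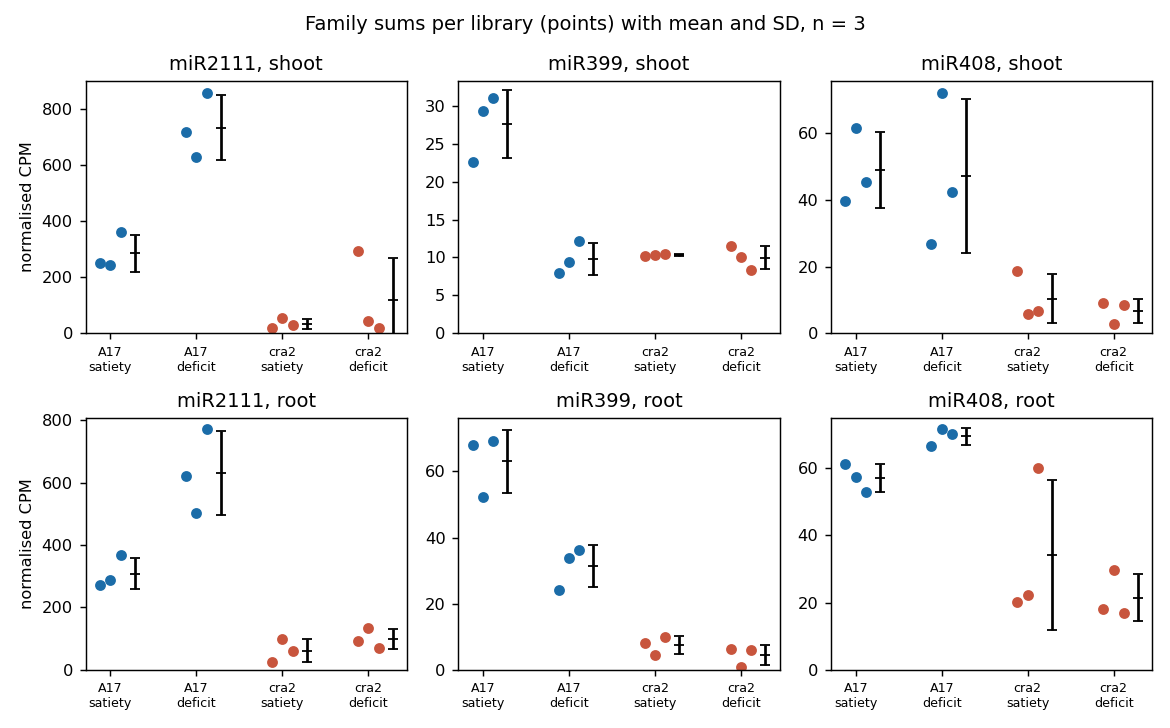
Normalised CPM of the miR2111, miR399 and miR408 families in each library (points) with the mean and SD of each group (n = 3); an SD bar that would pass below 0 is drawn from 0. Over 6 libraries per genotype, miR2111 averaged 508.7 CPM in A17 shoots and 75.6 in cra2 shoots, and 470.0 and 79.3 in roots.

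In A17 shoots, local nitrogen deficit lowered miR399, which targets the phosphate regulator PHO2. The family stood at 9.84 ± 2.13 normalised CPM under deficit and 27.7 ± 4.45 under satiety (n = 3 each), a log2 change of -1.49 ± 0.26 (SE; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.00799). This call was kept in 11 of 12 alternatives (edgeR or DESeq2 adjusted p up to 0.0869) and in 6 of 6 fits with 1 library left out. miR2111, a mobile shoot-to-root signal that targets the nodulation repressor TML, stood at 732 ± 115 against 285 ± 66.0 CPM without overlap of the libraries, log2 1.36 ± 0.72, and did not pass (edgeR adjusted p = 0.2001). No single sequence passed among 189 (edgeR smallest adjusted p = 0.0525). Of them 62 had an unadjusted p under 0.05 (24 higher, 38 lower under deficit) and DESeq2 called 38 (20 higher, 18 lower). No overlap was seen for 90 sequences (47.6%) between the 3 and 3 libraries, where 10% would by chance.

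The 5 shoot sequences with the smallest p, all at edgeR adjusted p = 0.0525, were lower under deficit: GGAGTGACACTGAGAACACAAG (log2 -1.496 ± 0.32; 816 ± 130 against 2302 ± 726 CPM), miR399 TGCCAAAGGAGAGCTGCTCTT (-2.91 ± 0.66), CAGAGTGCAGATACACGCATC (-2.09 ± 0.50), miR399 TGCCAAAGGAGATTTGCCCTG (-1.08 ± 0.27) and TTTGGTTAGTGTGCTGAATAT (-1.21 ± 0.31). Among the 27 families tested, 1 was called. Adjusting over the families alone called 3 and added miR5213 (-0.78) and miR396 (0.70), both at edgeR adjusted p = 0.0591 over all. Values without a call were miR171 -0.78 (164.8 ± 12.7 against 282 ± 33.8 CPM), AP2-targeting miR172 -0.76 (1748 ± 411 against 2954 ± 353) and auxin-response-factor-targeting miR160 -1.13 (184.5 ± 39.9 against 404 ± 134), with edgeR adjusted p of 0.0791, 0.0791 and 0.0942. Further values were miR390 0.41, miR398 -0.85, miR167 0.40, miR164 -0.42, miR169 0.29, miR156 0.24 and miR408 -0.05 (edgeR adjusted p 0.193 to 0.913). The sign of miR408 turned positive with RLE or upper-quartile scaling. The list of the systemic signal (7 miR2111 sequences, median 1.38) had 0 calls, and 0 adjusted over the list alone. Its camera adjusted p was 0.00237, or 0.466 with the correlation estimated. The phosphate list (3 miR399 sequences, median -2.58) had 0 calls, and 3 adjusted over the list alone. Camera gave it adjusted p = 0.00237, or 0.0564 with the estimated correlation. Adjusted over each list alone, 6 of 20 organ-development members (1 higher, 5 lower), 1 of 7 auxin and 1 of 8 phase-change members (both lower) and 1 of 3 small RNA machinery members (higher) passed, none over all. The copper, NF-YA and NB-LRR lists had none in either count, and camera adjusted p of these 7 lists was 0.0577 to 0.945. The number of shoot calls rested on the libraries fitted, with 70 for the 6 compared libraries alone. The main fit estimated its spread over all shoot libraries, and the cra2 deficit group had a median SD of log2 CPM of 0.61. In both A17 shoot groups it was 0.29. Leaving out that cra2 group gave many calls too, so the 0 calls of the main fit did not describe A17 shoots alone. In the fit of the 6 compared libraries miR2111 reached edgeR adjusted p = 0.00124 (0.00124 to 0.451 over its 12 alternatives).

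In distant A17 roots the local deficit raised miR319 and miR2111 and lowered miR168 and miR399. miR319, which targets TCP transcription factors, rose from 6123 ± 828 to 11990 ± 2973 CPM (n = 3 each; log2 0.97 ± 0.19, edgeR adjusted p = 0.00159), and AGO1-targeting miR168 fell from 13260 ± 1901 to 7403 ± 1192 (log2 -0.84 ± 0.18, edgeR adjusted p = 0.0035). miR2111 rose from 308 ± 50.8 to 632 ± 134 (1.03 ± 0.35, edgeR adjusted p = 0.0413), while miR399 fell from 63.1 ± 9.54 to 31.4 ± 6.29 (-1.01 ± 0.31, edgeR adjusted p = 0.023). Of the sequences 52 were called and 116 were not, with 25 higher and 27 lower, 28 of them in a family. DESeq2 called 50, and 75 sequences (44.6%; 10% by chance) did not overlap.

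Other root families that rose under deficit were miR5213 (0.81; 28860 ± 2676 against 16510 ± 1911 CPM), miR172 (0.71; 2965 ± 447 against 1808 ± 263), miR160 (0.98; 3506 ± 497 against 1781 ± 777), NAC-targeting miR164 (0.67; 7607 ± 1344 against 4789 ± 265) and GRAS-targeting miR171 (0.51), with edgeR adjusted p of 0.00686 to 0.0491. The miR171 sum in A17 roots was mostly its opposite arm, so its rise need not be that of the mature strand. Families that fell were miR2118, which targets NB-LRR transcripts (-0.70; 4692 ± 1043 against 7644 ± 340), miR1509 (-0.72; 120 ± 13.0 against 198 ± 63.5) and SPL-targeting miR156 (-0.58; 1149 ± 290 against 1721 ± 148), at edgeR adjusted p of 0.0134, 0.0375 and 0.0468. In all 12 of 27 families passed (13 adjusted over families alone). Root values without a call were miR390 -0.53, miR398 0.36, miR169 0.31, miR408 0.28 and miR167 -0.12 (edgeR adjusted p 0.0567 to 0.639), the last turning positive with upper-quartile scaling.

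The sequences that rose most were miR398 TGTGTTCTCAGGTCGCCCCTG (1.72 ± 0.43; 83.6 ± 13.3 against 25.3 ± 7.29 CPM), AGGTTGTTTCTTGAAGTGCAAGGC (1.62 ± 0.27; 121.5 ± 28.3 against 39.6 ± 4.43), miR164 TGGAGAAGCAGGGCACATGCT (1.36) and TGATAGTGTCAACTAGTACAG (1.28). After these came CGTGACAACACATCATTGGATGCA (1.205), miR319 TTGGACTGAAGGGAGCTCCCT (1.18; 4597 ± 1306 against 2032 ± 437), miR160 TGCCTGGCTCCCTGAATGCCA (1.13; 1844 ± 80.5 against 839.7 ± 299) and GAATTGATTATGTTTGGATACACT (1.10). With them rose the miR2111 sequences AGCCTCGGAGTGCGGATTATC (1.18), AGCCTTGGAATGCAGATTATC (1.15), TAATCTGCATCCTGAGGTTTA (1.04; 153 ± 50.6 against 74.4 ± 20.5) and GTCCTCGGGATACAGATTACT (1.02), all 12 at edgeR adjusted p of 0.000887 to 0.0354. The largest falls were miR399 TGCCAAAGGAGAGCTGCCCTG (-1.72; 4.87 ± 1.67 against 16.4 ± 3.13), CCAGTTCTGCGTTCATGTCCC (-1.39), and GGCATGGGATAGTAGGGAAGA (-1.18). Next were the miR168 opposite arm CCCGCCTTGCATCAACTGAAT (-1.16; 1816 ± 553 against 4055 ± 565), miR399 TGCCAAAGGAGATTTGCCCTG (-1.07) and TTTTCCAATTCTAAGTCTATC (-1.03). Smaller falls were seen for miR168 TCGCTTGGTGCAGGTCGGGAA (-0.82; 5194 ± 802 against 9196 ± 1448), miR1509 TTAATCTAGGAAAATACGGTG (-0.80), ACCGGATTTCCTTGATTAAAG (-0.79), miR2118 TTACCGATTCCACCCATTCCTA (-0.79) and miR1507 CCTCGTTCCATACATCATCTAG (-0.76), these 11 at edgeR adjusted p of 0.00192 to 0.0226. By list, 4 of 6 systemic-signal members were higher (5 adjusted over the list alone), 2 of 2 phosphate members lower (2 alone), 3 of 4 NB-LRR members lower (3 alone) and 2 of 3 small RNA machinery members lower (3 alone). Camera adjusted p of these 4 lists was 0.00725, 0.0395, 0.0331 and 0.0286, or 0.308, 0.257, 0.275 and 0.257 with the estimated correlation. The auxin list had 3 of 7 higher and 2 lower (5 alone), and organ development 4 of 17 higher and 4 lower (8 alone). Phase change had 1 of 7 higher and 1 lower (2 alone), copper 1 of 3 higher (1 alone) and NF-YA 0 of 5 (0 alone), with camera adjusted p of 0.252 to 0.719 for these 5. Several root family calls were easily lost with 1 library left out: of 6 such fits miR156 and miR171 passed in 1, miR399, miR164 and miR1509 in 2, miR172 and miR2118 in 3, miR160 in 4 and miR5213 in 5. miR2111 passed in 0 of the 6 fits with 1 library left out and in 9 of 11 other alternatives (edgeR or DESeq2 adjusted p 0.00206 to 0.264). The split of directions moved from 25 higher and 27 lower to 39 and 6 with upper-quartile scaling, whose median log2 change over all sequences was 0.27 against -0.00 with the main scaling.

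**Figure D2:**
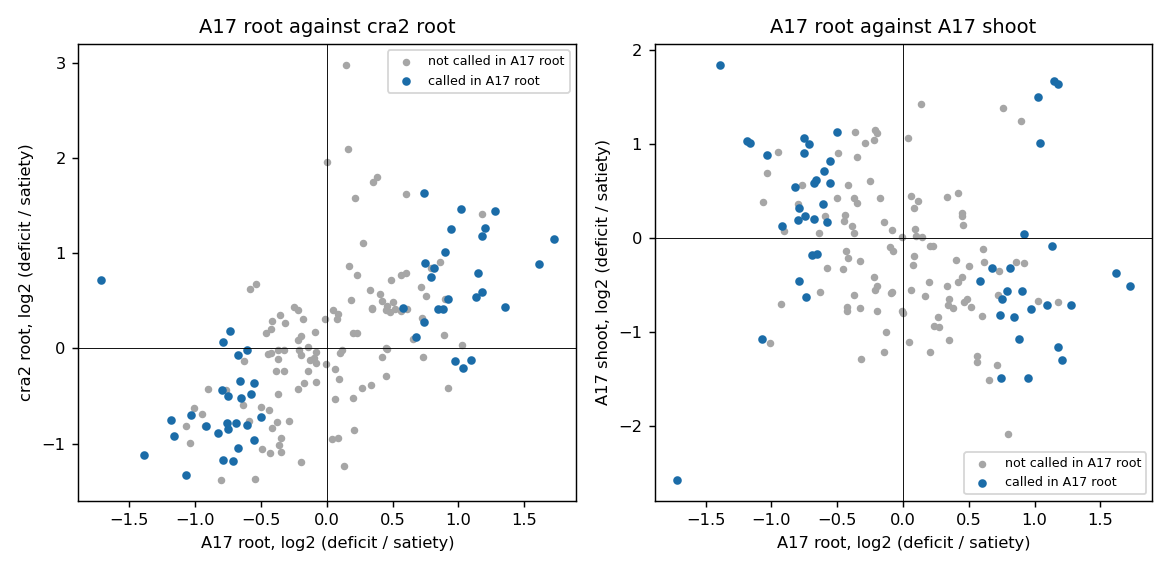
Log2 change under local nitrogen deficit of each sequence in A17 distant roots against that in cra2 distant roots (Pearson r = 0.613; 130 of the same sign, 38 not) and in A17 shoots (r = -0.280; 50 of the same sign, 107 not). Blue points are the sequences called in A17 roots, 52 against cra2 roots and, of those also tested in shoots, 24 higher and 27 lower against A17 shoots. Sequences are not independent replicates.

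The responses of the shoot and the distant root of A17 to the same local deficit differed for a part of the sequences. Of those tested in both organs 50 had the same sign and 107 did not, although no single shoot sequence was called in the main fit. Tested as a difference of the responses (shoot minus root, 24 libraries), 54 of 200 sequences passed, 17 positive and 37 negative, and DESeq2 called 58 (33 positive, 25 negative). The negative excess followed the scaling, since the median over all sequences was -0.31 with TMM and -0.01 with RLE, where 32 of 57 calls were positive. The signs of the 11 families called (6 positive, 5 negative; 13 adjusted over families alone) held with each of the 4 scalings, while with 1 library left out miR2118 passed in 3, miR1509 in 9 and miR166 in 11 of 12 fits. Of 11 other alternatives miR171, miR390, miR1509 and miR2118 each passed in 10 (edgeR or DESeq2 adjusted p up to 0.118, 0.0983, 0.168 and 0.0983).

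miR319, miR172, miR160 and miR171, higher under deficit in the root, had negative differences of -1.65 ± 0.36, -1.34 ± 0.35, -1.94 ± 0.55 and -1.14 ± 0.31, as had miR5213 (-1.44 ± 0.30), at edgeR adjusted p of 0.0025 to 0.0114. For miR171 the root sum was mostly the opposite arm, which made up little of the shoot sum. miR168 (1.73 ± 0.38), miR390 (1.11 ± 0.30), miR1507 (1.96 ± 0.55), miR166 (1.28 ± 0.37), miR1509 (1.13 ± 0.34) and miR2118 (1.27 ± 0.43) had positive differences, at edgeR adjusted p of 0.0025 to 0.0308. miR399 (-0.29 ± 0.43, adjusted p = 0.664) and miR2111 (0.47 ± 0.83, adjusted p = 0.720) did not pass, and the other 14 families lay between edgeR adjusted p 0.0538 and 0.993. The most positive sequences were CCAGTTCTGCGTTCATGTCCC (3.04), the miR168 opposite arm CCCGCCTTGCATCAACTGAAT (2.01), TTTTCCAATTCTAAGTCTATC (1.77) and TGGTTTTGGTCCTTGGTATTT (1.72). Following them were miR1507 CCTCGTTCCATACATCATCTAG (1.64), TTACCTATTCCACCAATTCCAT (1.55), and GGAATGTTGGCTGGCTCGAGG (1.503). Smaller positive differences were those of miR396 TTCCACAGCTTTCTTGAACTT (1.49), CTCGGCATTCATGTTTTTCCTT (1.36), TTGTCTTACCCATTCCTCCCA (1.23), miR168 TCGCTTGGTGCAGGTCGGGAA (1.22) and miR166 TCGGACCAGGCTTCATTCCCC (1.17). The most negative were AAAGTGGTGGGACATACATTGATT (-3.67), CAGAGTGCAGATACACGCATC (-3.01), miR171 TTGAGCCGTGCCAATATCACG (-2.74), and CGTGACAACACATCATTGGATGCA (-2.62). Also negative were TAATGGATTATGTAAGATTAA (-2.54), ACAGGGAACATGCAGAGCATG (-2.52), miR319 TTGGACTGAAGGGAGCTCCCT (-2.45), GGAGTGACACTGAGAACACAAG (-2.37), miR398 TGTGTTCTCAGGTCGCCCCTG (-2.35), miR160 TGCCTGGCTCCCTGTATGCCA (-2.30), TTGATCAAGGACTTTGCATC (-2.18) and AGGTTGTTTCTTGAAGTGCAAGGC (-2.11), all 24 at edgeR adjusted p of 0.000691 to 0.0345. In the lists, small RNA machinery had 2 of 3 positive (3 adjusted over the list alone) and NB-LRR 1 of 4 positive (3 alone), at camera adjusted p of 0.0205 and 0.0389, or 0.349 for both with the estimated correlation. Organ development had 3 of 22 positive and 7 negative (12 alone), and auxin 1 of 8 positive and 2 negative (6 alone). Copper had 1 of 3 negative (1 alone), phase change 1 of 8 negative (1 alone) and the systemic-signal, phosphate and NF-YA lists 0 (0 alone), camera adjusted p of these 7 being 0.689 to 0.865.

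In cra2 shoots no miRNA passed for the local deficit. edgeR called 0 of 189 sequences (smallest adjusted p = 0.450), and 12 had an unadjusted p under 0.05 (9 higher, 3 lower). DESeq2 called 0, while 18 sequences (9.5%; 10% by chance) did not overlap. miR399, lower under deficit in A17, stood at 9.97 ± 1.54 against 10.3 ± 0.152 CPM (n = 3 each; log2 -0.04 ± 0.27, edgeR adjusted p = 0.997; its sign turned with RLE scaling and library totals). miR2111 stood at 118 ± 151 against 33.1 ± 18.4 (1.84 ± 0.74, edgeR adjusted p = 0.723), with 291.45 CPM in replicate 1 under deficit and 16.61 to 52.99 in the 5 other cra2 shoot libraries.

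The 5 cra2 shoot sequences with the smallest p were the miR396 opposite arm GCTCAAGAAAGCTGTGGGAGA (-0.74; 426.7 ± 39.1 against 712 ± 94.9 CPM), ATCCAACGATGCGGGAGCTGC (-1.65), miR396 TTCCACAGCTTTCTTGAACTG (0.82; 22070 ± 8271 against 12470 ± 434) and the miR2111 sequences AGCCTCGGAGTGCGGATTATC (2.28) and ATCCTTAGAATGCAGATTATC (2.37), at edgeR adjusted p of 0.450 to 0.572. Family values were miR160 0.99 (480 ± 301 against 242 ± 56.2), miR398 0.80, miR172 0.34, miR156 0.08, miR164 0.08, miR390 -0.37, miR408 -0.64, miR167 -0.21, miR169 -0.22 and miR171 -0.03 (edgeR adjusted p 0.723 to 0.997). The last 3 turned positive with library totals, and miR171 also with RLE. The systemic-signal list (7 members, median 1.99) had 0 calls and 0 adjusted over the list alone, with camera adjusted p = 0.000112, or 0.729 with the estimated correlation. All 8 other lists had 0 calls, with 1 of 20 organ-development members lower adjusted over the list alone and 0 elsewhere, at camera adjusted p of 0.659 to 0.912. Replicates of the cra2 shoot deficit group spread more than those of any other shoot group.

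Distant cra2 roots also responded to the local deficit. miR319 rose from 3144 ± 311 to 7299 ± 557 CPM (n = 3 each; log2 1.21 ± 0.19, edgeR adjusted p = 6.15e-05), and miR398, which targets copper/zinc superoxide dismutases, rose from 376 ± 96.9 to 773 ± 284 (1.04 ± 0.24, edgeR adjusted p = 0.00358). miR2118 fell from 11690 ± 2773 to 6057 ± 457 (-0.95 ± 0.19, edgeR adjusted p = 0.00169) and miR168 from 11570 ± 1931 to 7242 ± 288.5 (-0.68 ± 0.18, edgeR adjusted p = 0.00599). Of the sequences 48 passed and 120 did not, with 23 higher and 25 lower, 18 in a family, against 46 by DESeq2. Without overlap were 69 sequences (41.1%; 10% by chance).

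Also called were miR164 (0.66; 4124 ± 326 against 2617 ± 540 CPM), miR172 (0.63; 1130 ± 109 against 729 ± 48.0), miR1510 (-0.72; 455 ± 35.0 against 749.5 ± 183) and miR166 (-0.50; 69970 ± 2511 against 98800 ± 12440), at edgeR adjusted p of 0.0104, 0.0117, 0.0104 and 0.0261. Thus 8 of 27 families passed (9 adjusted over families alone). Not called were miR2111 (0.68; 97.6 ± 32.2 against 61.1 ± 36.3), miR399 (-0.74; 4.396 ± 3.02 against 7.50 ± 2.75), miR160 0.55, miR408 -0.62, miR167 -0.13, miR390 0.21, miR156 0.15, miR171 0.03 and miR169 0.02 (edgeR adjusted p 0.120 to 0.960). The signs of the last 4 turned with upper-quartile scaling and those of the last 3 also with RLE. The largest rises were AGCTGCTGACTCGTTGGTTCA (2.98 ± 0.71; 237 ± 207 against 28.8 ± 20.6; 2.09 without replicate 3 of deficit), ACAAGTAGAACCTTTTTTCTG (2.10), miR169 CAGCCAAGGATGACTTGCCGG (1.96), and miR171 TGATTGAGTCGTGCCAATATC (1.80; 1.12 without that replicate). Others that rose were AGATTGAGACTTGTATGGCTT (1.75), GGAGTGACACTGAGAACACAAG (1.64 ± 0.25; 471 ± 70.2 against 151 ± 49.3), and miR319 TTGGACTGAAGGGAGCTCCCA (1.63). Below them stood TGTGGAGTCTTTTGCATGAAG (1.58), miR2111 GTCCTCGGGATACAGATTACT (1.47), TGATAGTGTCAACTAGTACAG (1.45), TTCGGGTTGATAATATTTTCTT (1.42) and CGTGACAACACATCATTGGATGCA (1.26). The largest falls were AAGCATTGTGGCATTGTGATTGGT (-1.38), TCTCAACAGGACGGATCACTA (-1.37), TTACCTATTCCACCAATTCCAT (-1.18; 2646 ± 228 against 6013 ± 440), miR2118 TTACCGATTCCACCCATTCCTA (-1.17; 5756 ± 585 against 12940 ± 2903), and CCAGTTCTGCGTTCATGTCCC (-1.12). Others that fell were CAACAGGACTCAAGCATTTCGC (-1.09), TGCTTACTCTCTATCTGTCACC (-1.06), TACATGTCGCTCTCACCTGAA (-1.05), CTCGGCATTCATGTTTTTCCTT (-1.02), TTGTCTTACCCATTCCTCCCA (-0.97), miR1510 ACATGGTCGGTATCCCTGGAA (-0.94) and the miR168 opposite arm CCCGCCTTGCATCAACTGAAT (-0.93), these 24 at edgeR adjusted p of 0.000131 to 0.0493. By list, 3 of 4 NB-LRR members (3 adjusted over the list alone) and 3 of 3 small RNA machinery members (3 alone) were lower, at camera adjusted p of 0.0142 and 0.0397, or 0.287 for both with the estimated correlation. Organ development had 5 of 17 higher and 3 lower (8 alone), and copper 1 of 3 higher (3 alone: 2 higher, 1 lower). Systemic signal had 1 of 6 higher (1 alone), NF-YA 1 of 5 higher (0 alone), auxin 1 of 7 lower (1 alone), and phosphate and phase change 0 (0 alone), with camera adjusted p of 0.423 to 0.842 for these 7. miR172 and miR164 passed in only 5 and 6 of 11 alternatives (edgeR or DESeq2 adjusted p 0.0116 to 0.599 and 0.00349 to 0.479), and in 0 and 1 of 6 fits with 1 library left out. Of the 11 alternatives miR168 and miR166 passed in 9 (edgeR or DESeq2 adjusted p up to 0.0601 and 0.160). miR1510 and miR398 passed in 10 (up to 0.0601 and 0.177). The miR398 change was 0.48 and not called (edgeR adjusted p = 0.214) without replicate 2 of cra2 deficit. The directions were 23 higher and 19 lower with RLE and 27 higher and 3 lower with library totals.

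Whether loss of CRA2 function altered the nitrogen response was tested as the difference of the responses, cra2 minus A17. In shoots no family passed, and the smallest adjusted p were those of miR399 (1.45 ± 0.37, edgeR adjusted p = 0.0624, or 0.0451 over the families alone) and miR160 (2.12 ± 0.62, adjusted p = 0.0719). The miR160 value rests in part on replicate 2 of cra2 deficit, where it was highest and for which root material stays open. edgeR called 0 of 189 shoot sequences (smallest adjusted p = 0.0698), while 51 had an unadjusted p under 0.05 (32 positive, 19 negative). DESeq2 called 26 (14 positive, 12 negative), all 24 libraries in the fit gave 27 positive and 2 negative, and library totals 13 positive and 0 negative. In roots edgeR called 0 sequences (smallest adjusted p = 0.376), 21 had an unadjusted p under 0.05 (11 positive, 10 negative) and DESeq2 called 0.

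In shoots the 5 sequences with the smallest p were CAGAGTGCAGATACACGCATC (3.06 ± 0.68), miR171 TTGAGCCGTGCCAATATCACG (2.78 ± 0.70), miR160 TGCCTGGCTCCCTGTATGCCA (2.50 ± 0.65), CTTTTCACTTTCGAACGGGTG (2.07 ± 0.53) and GGAGTGACACTGAGAACACAAG (1.92 ± 0.45), all at edgeR adjusted p = 0.0698. Family values in shoots were miR172 1.10 ± 0.37, miR390 -0.78 ± 0.29 and miR2111 0.48 ± 1.01, at edgeR adjusted p of 0.105, 0.120 and 0.776. The 7 other families fixed in advance (miR398, miR171, miR167, miR169, miR164, miR408, miR156) lay between edgeR adjusted p 0.159 and 0.828. In roots the 5 sequences were AGCTGCTGACTCGTTGGTTCA (2.84 ± 0.95), GCTGGAAGGTTTTGTAGGAAC (0.91 ± 0.28), GGAGTGACACTGAGAACACAAG (0.90 ± 0.34), ACCGGATTTCCTTGATTAAAG (0.85 ± 0.31) and the miR171 opposite arm CGATGTTGGTGAGGTTCAATC (-0.73 ± 0.27), at edgeR adjusted p = 0.376. miR2111 (-0.35 ± 0.51) and miR399 (0.27 ± 0.64, turning negative with upper-quartile scaling) had edgeR adjusted p of 0.831 and 0.891 in roots, and the 10 other fixed families lay between 0.338 and 0.993. The lists had 0 calls in both organs. Adjusted over each list alone, 5 of 20 organ-development members (3 positive, 2 negative), 2 of 3 small RNA machinery members (negative), 1 of 3 phosphate and 1 of 7 auxin members (positive) passed in shoots and 0 in roots. The lists had camera adjusted p of 0.163 to 0.842 in shoots and 0.789 to 0.93 in roots. Across the root sequences the responses of A17 and cra2, which share no library, correlated at Pearson r = 0.613 (Spearman rho = 0.679), with 130 of the same sign and 38 not. Called in both were 11 higher (3.42 expected; exact p = 3.89e-05) and 15 lower sequences (4.02 expected; exact p = 2.69e-08), and 0 in opposite directions. These exact p treat sequences as independent, which members of a family are not. For miR399 in shoots DESeq2 gave adjusted p = 0.0161 (0.0161 to 0.148 over its 10 alternatives), and without replicate 3 of cra2 deficit 46 shoot sequences were called, against 0 to 13 in the 11 other fits with 1 library left out.

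cra2 shoots held less miR2111 and miR408 than A17 shoots over both nitrogen regimes. miR408, which targets copper proteins such as plantacyanin and laccases, averaged 8.49 ± 5.51 against 48.1 ± 16.3 CPM (n = 6 each; log2 -2.53 ± 0.37, edgeR adjusted p = 0.00153). miR2111 averaged 75.6 ± 107 against 508.7 ± 259 (-2.87 ± 0.54, edgeR adjusted p = 0.00704), and the change was -3.74 without replicate 1 of cra2 deficit. The miR2111 call was kept in 9 of 10 alternatives (edgeR or DESeq2 adjusted p up to 0.0512) and in 12 of 12 fits with 1 library left out. Of 189 sequences 20 passed, 7 higher and 13 lower in cra2, 12 with a family, against 21 by DESeq2.

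miR399 was lower in cra2 shoots as well (-0.70 ± 0.19; 10.15 ± 0.9999 against 18.8 ± 10.3 CPM, edgeR adjusted p = 0.0435), a call kept in 2 of 10 alternatives (edgeR or DESeq2 adjusted p 0.0253 to 0.406). Group means were 10.3 in cra2 against 27.7 CPM in A17 under satiety and 9.97 against 9.84 under deficit, but the difference between the regimes did not pass (edgeR adjusted p = 0.0624). Values without a call were miR169 -0.77 (60.2 ± 16.0 against 103 ± 23.8; edgeR adjusted p = 0.0551), miR2119 -0.52, miR167 -0.39, miR171 0.24 and miR160 0.32, at adjusted p of 0.294 to 0.648. miR398 -0.26 (1077 ± 890 against 1300 ± 587), miR172 -0.07 and miR164 -0.01 turned positive with library totals, and miR390 0.06 and miR156 0.04 kept their sign with each scaling (edgeR adjusted p 0.795 to 0.99). In all 3 of 27 families passed, 4 adjusted over families alone. Without overlap were GCTAAACGGAATGAGGGTAGTCAT, higher in cra2 (3.29 ± 0.51; 4.24 ± 0.831 against 0.459 ± 0.498 CPM), and 5 others lower in cra2. Among these were the miR2111 sequences AGCCTTGGAATGCAGATTATC (-3.02 ± 0.47), ATCCTTGGAATGCAGATTATC (-2.99 ± 0.43; 16.1 ± 14.9 against 134.5 ± 70.1) and AGCCTTGGGATGCTGATTATC (-2.70 ± 0.47) and miR408 ATGCACTGCCTCTTCCCTGGC (-2.47 ± 0.38; 8.67 ± 5.61 against 47.1 ± 17.5), these 5 sequences at edgeR adjusted p of 0.000797 to 0.00169. The remaining one, miR399 TGCCAAAGGAGAGCTGCTCTT, had 57 counts in A17 and 1 in cra2, a ratio per total of 42.9 (95% counting interval 7.39 to 1723; edgeR adjusted p = 0.00701). By list, 7 of 7 systemic-signal members were lower (7 adjusted over the list alone; camera adjusted p = 3.37e-16, or 0.033 with the estimated correlation). Phosphate had 2 of 3 lower (2 alone), copper 2 of 3 lower (2 alone; camera adjusted p = 0.0121, or 0.175 with the estimated correlation) and phase change 1 of 8 higher (2 alone, 1 higher and 1 lower). NF-YA had 0 of 3 (2 alone, lower), and auxin, NB-LRR, organ development and small RNA machinery 0 (0 alone), camera adjusted p of these and of phosphate and phase change being 0.0905 to 0.9. Calls in this comparison ranged from 13 to 40 when 1 library was left out, 40 without replicate 3 of cra2 deficit.

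Distant roots of cra2 held less than A17 of miR399, miR2111, miR172 and the copper miRNAs miR398 and miR408. miR399 averaged 5.95 ± 3.09 against 47.3 ± 18.8 CPM (n = 6 each; log2 -2.95 ± 0.29, edgeR adjusted p = 4.52e-09) and miR2111 79.3 ± 36.6 against 470.0 ± 199 (-2.52 ± 0.27, edgeR adjusted p = 9.35e-07). miR172 fell short of A17 by -1.35 ± 0.13 (929 ± 232.5 against 2386 ± 713; edgeR adjusted p = 4.52e-09) and miR398 by -1.45 ± 0.17 (574.5 ± 289 against 1489 ± 284; edgeR adjusted p = 3.56e-07). Of the sequences 72 passed and 96 did not, with 31 higher and 41 lower in cra2, 30 in a family. DESeq2 called 72 (33 higher, 39 lower).

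Further root families lower in cra2 were miR2119 (-1.67 ± 0.21; 92.9 ± 31.7 against 288.5 ± 75.7 CPM), miR164 (-0.88 ± 0.13; 3370 ± 917 against 6198 ± 1770), miR319 (-0.84 ± 0.13; 5221 ± 2311 against 9054 ± 3758), NF-YA-targeting miR169 (-0.97 ± 0.18; 128 ± 32.6 against 253 ± 44.2) and miR408 (-1.24 ± 0.25; 27.9 ± 16.4 against 63.3 ± 7.47), at edgeR adjusted p of 6.85e-07 to 0.00023. TAS3-targeting miR390 was higher (0.77 ± 0.14; 1019 ± 160.5 against 606 ± 133), as were miR2118 (0.49 ± 0.13; 8875 ± 3562 against 6168 ± 1759) and miR167 (0.32 ± 0.12; 5170 ± 571 against 4150 ± 412), at edgeR adjusted p of 0.000112, 0.00511 and 0.0457. In all 12 of 27 families passed (13 adjusted over families alone). miR171 (-0.32), miR156 (0.25) and miR160 (-0.14) did not pass, at edgeR adjusted p of 0.0584 to 0.533. Sequences higher in cra2 without overlap were AAAAGAATACTCATACATAACATT (1.27), TGTAGAAAAAACAAAGGGCAA (1.26), TTAATCTAGGAAATTACACTCG (0.88; 2426 ± 416 against 1325 ± 260), TCGGCTGTACTGTCCTTCATG (0.88) and TTTGTATTGTTGACATGGCTT (0.74; 2205 ± 278 against 1319 ± 182), at edgeR adjusted p of 2.85e-05 to 0.00115. Lower were the unnamed ACAAAGACATTGGAAGGCTTA (-3.14 ± 0.29; 12.5 ± 6.45 against 113 ± 31.2), TACTTGGTGAATTGTTGGATC (-2.85 ± 0.20; 108 ± 57.1 against 724 ± 104), TCTAATTATTCACCAAGTAAA (-2.26) and GGAGTGACACTGAGAACACAAG (-2.02 ± 0.18; 311 ± 184 against 1118 ± 355). Named ones were the miR172 opposite arm GTAGCATCATCAAGATTCACA (-2.47) and miR399 TGCCAAAGGAGATTTGCCCTG (-2.47). The miR2111 sequences GTCCTCGGGATACAGATTACT (-2.89), AGCCTCGGAGTGCGGATTATC (-2.62), ATCCTTGGAATGCAGATTATC (-2.56), TAATCTGCATCCTGAGGTTTA (-2.40; 20.5 ± 6.1 against 114 ± 55.1), AGCCTTGGAATGCAGATTATC (-2.35) and ATCCTTAGAATGCAGATTATC (-2.22) joined them, all 12 lower sequences at edgeR adjusted p of 6.78e-10 to 1.19e-05. By list, 6 of 6 systemic-signal members were lower (6 adjusted over the list alone; camera adjusted p = 2.05e-07, or 0.166 with the estimated correlation), as were 2 of 2 phosphate (2 alone), 3 of 3 copper (3 alone) and 3 of 5 NF-YA members (3 alone). Phase change had 1 of 7 higher and 3 lower (6 alone), and auxin 2 of 7 higher and 2 lower (5 alone). Organ development had 1 of 17 higher and 4 lower (5 alone), NB-LRR 2 of 4 higher (2 alone) and small RNA machinery 0 of 3 (0 alone), camera adjusted p of all but the systemic signal being 0.0621 to 0.555. miR167 was the least secure call, kept in 7 of 10 alternatives (edgeR or DESeq2 adjusted p 0.00991 to 0.495). It was kept in only 4 of 12 fits with 1 library left out (edgeR adjusted p 0.0212 to 0.367).

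**Figure D3:**
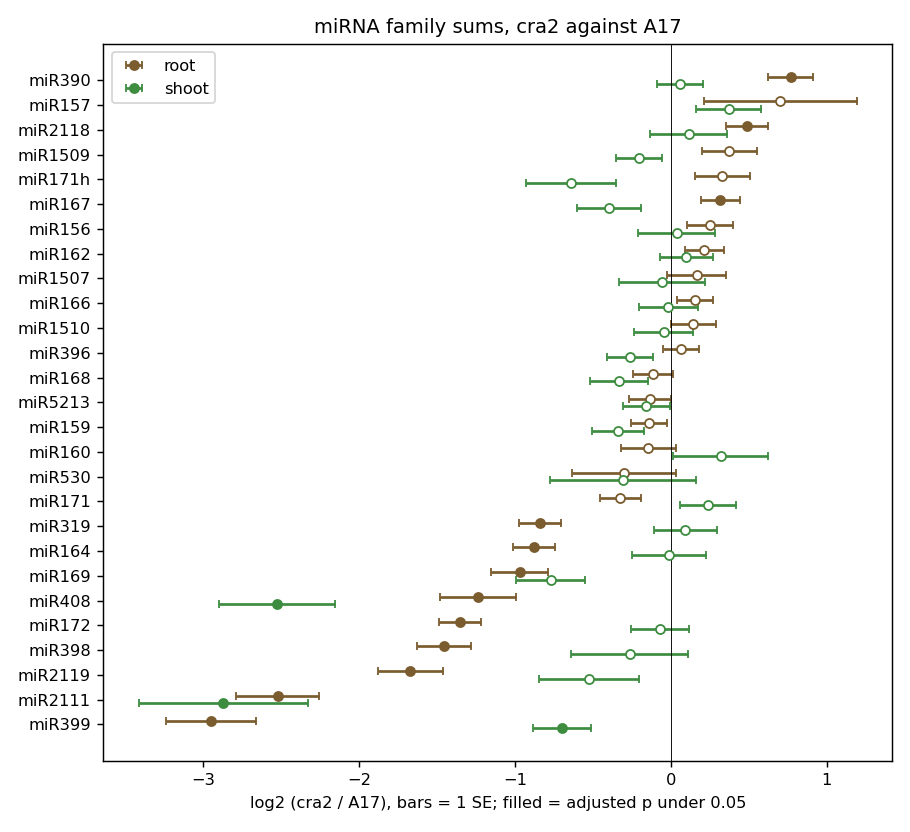
Log2 change between cra2 and A17 (± SE, n = 6 libraries per genotype) of the 27 families tested, in distant roots and in shoots, filled where the edgeR adjusted p is under 0.05 (12 families in roots, 3 in shoots). miR399 was -2.95 in roots and -0.70 in shoots.

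The genotype effects of shoot and root overlapped. Across the sequences tested in both they correlated at r = 0.643 (rho = 0.434), with 104 of the same sign and 53 not. Of them 10 were lower in cra2 in both organs (2.66 expected; exact p = 2.3e-06) and 3 higher in both (0.92 expected; exact p = 0.0441). These exact p treat sequences as independent. All 7 miR2111 sequences tested in shoots and all 6 in roots were called lower, so the same family is counted repeatedly, mostly by its opposite arm. A test of the difference of the genotype effects (root minus shoot, 24 libraries), added after the values were seen, called 17 of 200 sequences and 4 families. These were miR399 (-2.23 ± 0.35, edgeR adjusted p = 8.26e-05), miR172 (-1.30 ± 0.25, adjusted p = 0.00083), miR319 (-0.93 ± 0.25, adjusted p = 0.0282) and miR390 (0.71 ± 0.21, adjusted p = 0.0395). miR408 (1.31), miR398 (-1.16) and miR2119 (-1.13), all at edgeR adjusted p = 0.0842, and miR2111 (0.39, adjusted p = 0.743) did not pass that test.

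Shoots and distant roots of A17 were set apart by the SPL-targeting miR156 and miR157, abundant in shoots, and by miR160 and miR171h, abundant in roots. In the 24-library fit, whose CPM are scaled apart from those above, miR156 averaged 11790 ± 2988 CPM in shoots and 1116 ± 292 in roots (n = 6 each; log2 3.42 ± 0.27, edgeR adjusted p = 1.28e-10) and miR157 6831 ± 1975 and 613 ± 256 (3.53 ± 0.40, edgeR adjusted p = 9.71e-08). miR160 averaged 397.7 ± 183 and 2062 ± 891 (-2.37 ± 0.28, edgeR adjusted p = 1.41e-07), and miR171h, which targets NSP2, 15.6 ± 2.89 and 186 ± 52.3 (-3.57 ± 0.27, edgeR adjusted p = 8.33e-11). Of 200 sequences 120 passed, 56 higher and 64 lower in shoots, 45 with a family. DESeq2 called 127 (65 higher, 62 lower), and with library totals alone 29 were higher and 117 lower.

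Also higher in shoots were miR167 (1.43 ± 0.20; 8830 ± 3029 against 3225 ± 209 CPM), miR159 (1.12 ± 0.16), miR2118 (1.28 ± 0.22; 11540 ± 4198 against 4818 ± 1407) and miR2119 (0.95 ± 0.29; 432 ± 229 against 223 ± 53.1), at edgeR adjusted p of 1.15e-06 to 0.00668. miR172 (0.78), miR1510 (0.66), miR168 (0.65) and miR396 (0.57) were higher at edgeR adjusted p of 0.000463 to 0.00509, but with library totals their values turned to -0.14, -0.28, -0.30 and -0.38. With that scaling miR396 was called in the other direction, lower in shoots (edgeR adjusted p = 0.0257). With library totals miR2118 (0.34) and miR2119 (0.0037) lost their calls, at edgeR adjusted p of 0.127 and 0.989, and miR167 and miR159 kept theirs at 0.46 and 0.18. Lower in shoots were the family sums of miR171 (-1.34 ± 0.16; 304 ± 81.7 against 762 ± 195), miR390 (-0.93 ± 0.15; 249 ± 61.1 against 472 ± 104.5), miR1509 (-0.74), miR5213 (-0.58), miR162 (-0.66), which targets DCL1, and miR399 (-0.60 ± 0.21; 25.2 ± 12.6 against 36.8 ± 14.6), at edgeR adjusted p of 9.71e-08 to 0.0192. The miR171 sum in roots was mostly its opposite arm, and mature miR171 sequences named below were higher in shoots. The miR399 call was kept in 8 of 12 fits with 1 library left out (edgeR adjusted p 0.01375 to 0.0673). In all 18 of 27 families passed (10 higher, 8 lower; 19 adjusted over families alone). miR2111 (0.87; turning to -0.07 with library totals) was at edgeR adjusted p = 0.0779, and miR169, miR398, miR164 and miR408 were between 0.0666 and 0.21.

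Shoot-enriched sequences included miR171 TGATTGAGCCGTGCCAATATT (657 counts against 1, ratio per total 285.9, 95% counting interval 51.1 to 11310) and TGATTGAGCCGTGCCAATATC (667 against 1, ratio 290.3, interval 51.9 to 11480), with TATTGCACTCATCTTCCATGGC (at least 46.2-fold) and CTTTTCACTTTCGAACGGGTG (at least 29.1-fold), both without a count in A17 roots. Others were GGAAAACATGAATGTCGGGTG (7.19), GCTCTCTAGACTTCTGTCATC (5.34; 2639 ± 1077 against 62.5 ± 25.6 CPM), ATCCAACGATGCGGGAGCTGC (4.97), miR157 TTGACAGAAGATAGAGGGCAC (4.18; 5944 ± 1219 against 348 ± 159.4), TGCTTACTCTCTATCTGTCACC (3.95), AGCTGCTGACTCGTTGGTTCA (3.77), TTCGGGTTGATAATATTTTCTT (3.73) and AAAAGAATACTCATACATAACATT (3.36), all 12 at edgeR adjusted p of 1.18e-13 to 3.06e-06. Root-enriched sequences were miR319 ATTGGAGTGAAGGGAGCTCCA (at least 66.9-fold) and TGTAGAAAAAACAAAGGGCAA (at least 62.2-fold), both without a count in A17 shoots, and TTGCAGACAGCTTTGAAGGTT (54 against 2 counts, ratio 62.0, interval 16.4 to 525.3). Others were TAGAGATTTGTTTAACAGCCA (-7.03), miR164 TGGAGAAGCAGGGCACATGCT (-4.94), CCAAGGAAATAGATATCCAGC (-4.76), the miR171 opposite arm CGATGTTGGTGAGGTTCAATC (-4.54; 28.6 ± 8.38 against 663 ± 164.1), miR169 CAGCCAAGGGTGATTTGCCGG (-4.37), miR160 TGCCTGGCTCCCTGAATGCCA (-4.07; 57.9 ± 11.4 against 1053 ± 466), ATGGGATCCTGTTGGTGGGTTAC (-3.72), miR171h CGAGCCGAATCAATATCACTC (-3.63) and TCTCAACAGGACGGATCACTA (-3.56), these 12 at edgeR adjusted p of 2.23e-15 to 5.63e-06. The counting intervals and the at-least values cover counting error only. The miR171 opposite arm, at 663 CPM in A17 roots, made up most of the family sum there (762 CPM, scaled apart). The lower miR171 sum of shoots therefore describes mainly that arm. The mature miR171 sequences with 657 and 667 counts in A17 shoots had 1 count each in A17 roots. The family without its opposite arm was not tested. By list, organ development had 9 of 22 higher and 8 lower (18 adjusted over the list alone), phase change 4 of 8 higher and 1 lower (5 alone) and auxin 2 of 8 higher and 4 lower (6 alone). NF-YA had 1 of 5 higher and 3 lower (4 alone), NB-LRR 2 of 4 higher and 1 lower (3 alone) and small RNA machinery 2 of 3 higher and 1 lower (3 alone). Phosphate had 2 of 3 lower (3 alone), systemic signal 2 of 6 higher (1 alone) and copper 0 of 3 (0 alone), at camera adjusted p of 0.242 to 0.848 over the lists. With library totals the median log2 change of all sequences was -0.95 against -0.09 with the main scaling.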

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

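The tests of GC content, of sequence length and of variation among replicates, and the re-divisions of libraries unless stated otherwise, had limits set before their values were computed. The tests of depth for the differing responses, all tests of the cra2 pattern, and those of root material and of an A17 sample were chosen after the result was seen. The limits for root material in replicate 2 and for an A17 sample were rewritten once their values were known, which moved both explanations from excluded to open, and the tests of miR399 in shoots were added at the same time.

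The differing nitrogen responses of A17 shoots and roots could come from a technical gradient, but most tests argue against it. The difference of the responses correlated with GC content at Spearman rho = 0.0954 and with sequence length at rho = -0.0445 across 200 sequences, and thinning all libraries to the smallest total gave 46 calls, against 54 before. The leading axis of differences among replicates, which held 23.7% of that variance, correlated with the difference of the responses at r = 0.494, just under the limit of 0.5 set for it, so a shared axis of variation between samples stays open (r = 0.572 with A17 libraries alone, 0.286 with cra2 libraries alone, and 0.522 between the axis and the A17 root response itself). Exchanging nitrogen labels within each organ, a test added after the first, gave as many calls in 1 of 100 divisions (the real one; highest other 15), whereas exchanging organ labels gave as many in 11 of 100 (highest other 120), since such divisions mix the organs. The responses may therefore reflect organ-specific regulation by the local deficit, or partly a state in which the sampled plants differed.

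The lower miR2111 and miR408 of both organs and miR399 of roots in cra2 were not explained by the technical causes tested. Among these 5 family changes, the one nearest 0 was -1.26 after thinning to equal totals and -1.37 without the dominant miR159 sequence. miR399 in shoots lost its call in both fits, though its change there (-0.77 and -0.67) stayed close to the -0.70 of the main fit. Its main call was itself near the limit (edgeR adjusted p = 0.0435), so a lost call cannot decide, and depth and the dominant sequence stay open for it. No miR2111 sequence was higher in cra2, the highest value being -2.22. Counts moved between near-identical miR2111 sequences would leave the family sum unchanged, so this test could not bear on the lower sum. Loss of CRA2 signalling may underlie the 5 changes, with miR399 and miR408 linking it to phosphate and copper status, but the genotype labels were not checked and no nutrient was measured. Divisions that mixed genotypes gave as many calls only for the real one, 1 of 100 in shoots (20 calls; highest other 9) and 1 of 100 in roots (72 calls; highest other 18).

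The 3 cra2 shoot libraries under deficit spread more than other shoot groups, with a median SD of log2 CPM of 0.61 against 0.29 to 0.31. After thinning the ratio to the highest other group was 1.77 (1.99 before), so depth is unlikely to be the cause. Root material in replicate 3 is unlikely, as its 9 root-enriched sequences summed to 0.741 of the highest of the 9 shoot libraries outside this group. In replicate 2 that ratio was 4.44, with 6 of the 9 above all other shoot libraries, yet CGATGTTGGTGAGGTTCAATC had 67 counts where 172.8 would be needed with the profile of cra2 roots, so root material stays open. An A17 sample stays open too, since miR408 reached at most 0.333 of the lowest A17 shoot library, but miR2111 in replicate 1 (291.45 CPM) lay in the A17 range (244.26 to 854.01). In that same replicate miR408 was 8.93 CPM, below every A17 shoot library (26.85 to 72.27), so the families disagreed for it.

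Called differences between the shoot and root responses of A17 (shoot minus root, edgeR) numbered 54. The positive ones named were CCAGTTCTGCGTTCATGTCCC 3.04, CCCGCCTTGCATCAACTGAAT 2.01, TTTTCCAATTCTAAGTCTATC 1.77, TGGTTTTGGTCCTTGGTATTT 1.72, CCTCGTTCCATACATCATCTAG 1.64, TTACCTATTCCACCAATTCCAT 1.55, GGAATGTTGGCTGGCTCGAGG 1.503, TTCCACAGCTTTCTTGAACTT 1.49, CTCGGCATTCATGTTTTTCCTT 1.36, TTGTCTTACCCATTCCTCCCA 1.23, TCGCTTGGTGCAGGTCGGGAA 1.22 and TCGGACCAGGCTTCATTCCCC 1.17. The negative ones were AAAGTGGTGGGACATACATTGATT -3.67, CAGAGTGCAGATACACGCATC -3.01, TTGAGCCGTGCCAATATCACG -2.74, CGTGACAACACATCATTGGATGCA -2.62, TAATGGATTATGTAAGATTAA -2.54, ACAGGGAACATGCAGAGCATG -2.52, TTGGACTGAAGGGAGCTCCCT -2.45, GGAGTGACACTGAGAACACAAG -2.37, TGTGTTCTCAGGTCGCCCCTG -2.35, TGCCTGGCTCCCTGTATGCCA -2.30, TTGATCAAGGACTTTGCATC -2.18 and AGGTTGTTTCTTGAAGTGCAAGGC -2.11. Families were miR5213 -1.44, miR319 -1.65, miR168 1.73, miR172 -1.34, miR390 1.11, miR171 -1.14, miR160 -1.94, miR1507 1.96, miR166 1.28, miR1509 1.13 and miR2118 1.27. Genotype effects differed between root and shoot (root minus shoot) for miR172 -1.30, miR319 -0.93, miR390 0.71 and miR399 -2.23. Dividing the libraries otherwise gave as many calls as observed in 10 of 10 divisions for the A17 shoot response (0 calls), 1 of 10 for the A17 root response (52; highest other 0), 10 of 10 for cra2 shoots (0; highest other 5) and 1 of 10 for cra2 roots (48; highest other 0). For the differences of responses between genotypes it was 100 of 100 in both organs (0 calls; highest other 9 in shoots and 10 in roots), and 1 of 100 for shoot against root (120; highest other 82). Where 0 calls were observed every division gives as many, so those shares decide nothing. With 10 divisions no share can fall under 0.05, so 1 of 10 cannot decide either. At edgeR unadjusted p under 0.05 the real division had 62 sequences in A17 shoots (highest other 14) and 12 in cra2 shoots (33). For the differences between genotypes it had 51 in shoots (50) and 21 in roots (49).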

How the results depend on the processing

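Thinning, leaving out the miR159 sequence and leaving out the 3 cra2 shoot deficit libraries were chosen after the results were seen; the other alternatives were chosen before the data were examined. The weakest result was the number of calls in A17 shoots, 0 in the main test, which was 6 with RLE, 1 with library totals, 38 with DESeq2, 5 without a filter, 8 with at least 10 CPM in 3 libraries, 6 with family sums, 35 with all 24 libraries, 70 with the 6 compared, 4 thinned and 65 without the 3 cra2 shoot deficit libraries. A17 roots had 52 calls and 19 with all 24 libraries. cra2 roots had 48 and 30 with library totals. The difference of responses between genotypes in shoots had 0, and 13 with library totals, 26 with DESeq2, 2 without a filter, 29 with all 24 libraries and 2 thinned. cra2 against A17 in shoots had 20, and 9 with at least 10 CPM, 8 with family sums and 10 thinned. With 1 library left out, calls ranged from 16 to 46 (A17 roots), 0 to 5 (A17 shoots), 25 to 50 (cra2 roots), 0 to 6 (cra2 shoots), 0 to 46 and 0 to 1 (difference between genotypes, shoots and roots) and 13 to 40 (cra2 against A17, shoots). With the replicate number as a block, calls were 0 (A17 shoots), 0 (cra2 shoots), 47 (cra2 roots), 16 and 76 (genotype, shoots and roots), 120 (shoot against root) and 60 (difference of responses between organs).

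Signs turned only for families without a call in the main test, apart from shoot against root with library totals: miR1510 -0.28, miR168 -0.30, miR172 -0.14, miR396 -0.38 and the uncalled miR2111 -0.066. The log2 changes that turned are given per setting. For the A17 response, miR408 in shoots was 0.0089 (DESeq2), 1e-04 (RLE), 0.17 (24 libraries), 0.10 (10 CPM), 0.11 (thinned) and 0.21 (upper quartile), and miR167 in roots 0.081 (upper quartile). For cra2 shoots, DESeq2 gave miR171 0.018 and miR399 0.0104. RLE gave 0.0083 and 1e-04, 10 CPM 0.023 and 0.017, and thinning 0.049 and 0.17. Library totals gave 0.39 and 0.34 with miR167 0.13 and miR169 0.27, and the replicate block gave miR156 -0.035. For cra2 roots, miR169 and miR171 were -0.12 and -0.12 (6 libraries), -0.094 and -0.089 (DESeq2), -0.13 and -0.13 (RLE), -0.061 and -0.0596 (24 libraries), -0.14 and -0.14 (no filter) and -0.43 and -0.44 (upper quartile). In them miR156 was -0.011 (RLE), -0.027 (no filter) and -0.32 (upper quartile), and miR390 -0.25 (upper quartile). For cra2 against A17 shoots, miR164 was 0.061 (DESeq2), 0.078 (RLE), 0.037 (10 CPM), 0.073 (thinned), 0.29 (library totals), 0.15 (upper quartile) and 0.033 (without miR159). miR172 was 0.0097 (RLE), 0.0027 (thinned), 0.26 (library totals) and 0.054 (upper quartile). miR398 was 0.013 (library totals), miR390 -0.036 (24 libraries), and miR156 -0.044 (24 libraries) and -0.0047 (replicate block). For the difference of responses between genotypes in roots, miR399 was -0.059 (thinned) and -0.39 (upper quartile). With 1 library left out miR408 ranged from -0.61 to 0.24 in A17 shoots. In cra2 shoots the ranges were miR156 -0.61 to 0.39, miR164 -0.52 to 0.36, miR169 -0.49 to 0.06, miR171 -0.21 to 0.15, miR2111 -0.0315 to 2.44, miR398 -0.32 to 1.12, miR399 -0.12 to 0.0441 and miR408 -0.90 to 0.0902. In cra2 roots they were miR156 -0.17 to 0.19, miR169 -0.58 to 0.0058, miR171 -0.29 to -0.0816 and miR390 -0.10 to 0.22. For cra2 against A17 shoots they were miR156 -0.26 to 0.24, miR164 -0.26 to 0.18 and miR172 -0.083 to 0.10, and in roots miR160 -0.34 to 0.0812. For the difference between genotypes they were miR2111 in shoots -1.34 to 1.10 and miR399 in roots -0.30 to 0.71.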

Other observations

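The relations between families and the test of library totals were chosen after the results were seen. The limit for these relations was also rewritten once their values were known, by asking for r above 0.3 without the 2 farthest libraries, which moved the origin of the sequence below from supported to open. An unnamed sequence, GGAGTGACACTGAGAACACAAG, was compared with the miR398 family. It was called higher under deficit in cra2 roots and lower in cra2 than in A17 roots, as miR398 was, and its fall under deficit in A17 shoots was not called (edgeR adjusted p = 0.0525). Its log2 CPM correlated with miR398 at Pearson r = 0.884 in A17 shoots, 0.86 in cra2 shoots, 0.784 in A17 roots and 0.799 in cra2 roots (n = 6 each; exact permutation p 0.0389, 0.0347, 0.075 and 0.0542; Benjamini-Hochberg adjusted over 8 relations 0.104 to 0.12). Spearman rho was 0.829, 0.6, 0.543 and 0.771, and without the 2 farthest libraries r was 0.749, -0.446, 0.832 and 0.984, so the relation in cra2 shoots rested on those samples. Each set of 6 held both nitrogen regimes, and the permutations ignored them, so these r cannot be told from a shared response to deficit. In cra2 roots both the sequence and miR398 were higher under deficit without overlap. With an 11-nt run complementary to miR398, the sequence may be the opposite arm of a miR398 precursor, for which r above 0.7 was asked in each set (lowest 0.784). This stays open, since r in cra2 shoots did not hold without the 2 farthest libraries.

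miR2119 and miR398 share a transcript in legumes, and both were lower in cra2 roots. Their correlations were r = 0.731 (A17 shoots), 0.337 (cra2 shoots), 0.349 (A17 roots) and 0.946 (cra2 roots), with exact permutation p of 0.1, 0.517, 0.497 and 0.00972 (adjusted 0.0778 to 0.517). These sets held both nitrogen regimes too. In cra2 roots miR2119 (113 ± 32.1 CPM under deficit, 72.6 ± 15.9 under satiety) and miR398 both differed between regimes without overlap, which alone can raise r. Without the 2 farthest libraries r was 0.747, 0.891, 0.541 and 0.695 in the same order. The lowest over all 6 libraries, 0.337, lay between the limits set, so a common transcript may or may not explain the shared fall in cra2 roots.

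Library totals were lower in cra2 than in A17. In roots they averaged 1044106 ± 162684 against 1526818 ± 126992 counts (n = 6 each; exact permutation p = 0.002165, two-sided, the smallest this design can give), with the highest cra2 total (1163545) below the lowest A17 total (1358742). In shoots they averaged 2639461 ± 723633 against 3508286 ± 402043 (exact permutation p = 0.02165). Totals depend on how libraries were pooled as well as on RNA content, and thinning to equal totals left the nearest to 0 of 5 family changes at -1.26.

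The relation of the A17 root response to that of cra2 shoots was also positive (r = 0.544; 108 sequences of the same sign, 49 not), while the A17 shoot response correlated at -0.481 with that of cra2 roots. A17 shoots thus stood apart from the 3 other responses, with r of 0.0576 to that of cra2 shoots across 189 sequences and -0.280 to that of A17 roots. As cra2 shoots had no called sequence and the difference between genotypes in shoots called 0, this contrast is a question for more samples, since leaving out replicate 3 of cra2 deficit gave 46 calls and leaving out any other library gave 0 to 13.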
